A study of Homo sapiens with 26 samples.

How the data were processed

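Messenger RNA was measured in 26 human breast samples with Affymetrix Human Genome U133 arrays (the A chip of the set), 1 array per sample and 1 colour. The labels give 9 normal fractions (3 donors with a CD10+, a BerEp4+ and a stromal fraction each), 3 samples of tumour cells from pleural effusions, 4 immortalized mammary epithelial (HMEC) lines and 10 breast cancer lines. Per the labels, RNA was isolated with PicoPure, labelled with the NuGEN Ovation biotin system and hybridised. The normal fractions and effusion tumours were not cultured, and tumour cells were enriched from effusions by centrifuging and by filtering for cell clusters. HMEC lines and cancer lines were grown in separate media. The deposited values are log2 values that the authors made with RMA, which subtracts background, equalises the distributions of the arrays and combines the probes of a probe set. The version of the software and the genome build are not given in the sources used here. Array medians lay between 5.713 and 5.83 and values between 3.03 and 14.28. No array was left out.

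Probe sets were joined to gene symbols by the platform table. Of 22283 probe sets, 1043 carried several symbols, 2169 none and 19071 1 symbol. Of all, 68 were controls, and a control with a symbol stood for GAPDH. A further 31 were left out because they measure genes that tell the sex of a person, which left 19040 probe sets for 11939 genes. Each gene was represented by the probe set with the highest mean over the 26 arrays, a choice that mattered for the 4304 genes with more than 1. Genes without a probe set among these, such as GLS and GLS2, were not analysed here.

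Samples were grouped by the labels. Cancer lines were further classed as triple-negative (HCC1187, HCC3153, BT20, BT549 and MDA-MB-231) or oestrogen receptor-positive (MCF7, ZR_75-30, BT474 and BT483) from textbook knowledge, which the labels do not give. The line labelled T74D matched no line name with certainty and was left without a class. The comparisons were BerEp4+ against CD10+ epithelium, stroma against epithelium (both fractions), HMEC lines against epithelium, effusion tumours against epithelium, cancer lines against HMEC lines, effusion tumours against cancer lines, triple-negative against oestrogen receptor-positive lines, and the difference between cancer minus HMEC lines and effusion tumours minus epithelium. Each was a contrast of a linear model in limma 3.58.1 under R 4.3.3, with moderated t statistics and p-values adjusted by Benjamini and Hochberg over all genes. A gene passed at an adjusted p of 0.05. The model of the first comparison held 6 groups and all 26 samples, that of triple-negative against receptor-positive lines held the 9 lines alone, and the others held 5 groups and all 26 samples. In each fit the spread was pooled over all its groups. For 17 genes fixed in advance, triple-negative and receptor-positive lines were also compared with an exact two-sided permutation test over all 126 splits, with an adjustment over the 17 genes; the smallest p it can give is 0.00794.

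Gene lists were written by hand from general knowledge before any comparison was run. The 28 lists held 496 entries, of which 441 were measured: adipocyte, amino acid response and serine synthesis, antigen presentation, basal and myoepithelial, cell cycle, cholesterol synthesis, cystine and glutathione, dissociation and immediate-early, endothelial, ERBB2 amplicon, erythrocyte, fatty acid synthesis, fibroblast and matrix, glutamine metabolism, glycolysis, hypoxia, inflammatory cytokine, interferon response, luminal, lymphocyte, macrophage and monocyte, mesenchymal, mesothelial, milk and secretory, NRF2 target, oestrogen response, oxidative phosphorylation and squamous differentiation genes. Lists were tested against all other genes with camera in limma, with a preset correlation between genes of 0.01 and again with the correlation estimated from the data, and adjusted over the lists of each comparison. A list was called when the first of these passed an adjusted p of 0.05. Members were also adjusted over their list alone.

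Genes were named by a rule fixed before the data were examined: up to 10 largest rises and 10 largest falls past the threshold whose groups did not overlap, up to 4 members with the largest difference in each described list, and a fixed set (SLC7A11, SLC3A2, GCLC, GCLM, GLS, GLS2, GLUL, SLC1A5, SLC7A5, ASNS, PHGDH and MYC, with MME and EPCAM for the normal fractions and ESR1, PGR, ERBB2, KRT5 and VIM for the lines). Overlap was not examined in the last comparison. The text names fewer genes than the rule admits. The alternatives tried were another choice of probe set (the median of all, or without those ending in _x_at or _s_at), leaving out the dimmest 25% of genes, each array centred on its median, a repeated quantile normalization, array weights, a trended and robust prior of the variance, only the compared samples in the fit (for the line classes, all 26), the epithelial fractions as separate groups or averaged per donor, the donor as a replicate block or random block, HMEC lines averaged by laboratory, T74D counted as receptor-positive, both HER2-amplified lines left out, and leaving out each sample in turn. A further pair, chosen after seeing the data, used the difference between the 3-prime and 5-prime GAPDH control probe sets as a covariate or left out both normal samples in which it was largest. Other splits of the samples, at most 100 per comparison, were drawn with a fixed seed, also with the epithelial fractions averaged per donor and HMEC lines by laboratory.

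The procedure was tested on simulated data with the groups, spread and sample numbers of these data. At a log2 difference of 1, from 38% (BerEp4+ against CD10+, and the last comparison) to 61% (cancer against HMEC lines) of changed genes were called, and at 2 from 67% to 93%. Tables were made with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and figures with matplotlib 3.10.9.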

Results

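Messenger RNA was measured on 26 human breast samples, each on 1 array. From dissociated normal breast tissue, 3 donors each gave a CD10+ epithelial fraction, a BerEp4+ epithelial fraction and a stromal fraction, all purified without culture. Tumour cells from pleural effusions gave 3 uncultured samples. The 4 human mammary epithelial cell (HMEC) lines were HMLE, HMLE-PR, 184A1 and 184B5, which are immortalized but not tumour lines. The 10 cancer lines were HCC1187, HCC3153, BT20, BT549 and MDA-MB-231, counted here as triple-negative (5 lines), MCF7, ZR_75-30, BT474 and BT483, counted as oestrogen receptor-positive (4 lines), and 1 line labelled T74D, which was left unclassed. These receptor classes are textbook knowledge and are not given in the labels. Values are log2 RMA values, and the number of arrays limits the precision. Differences below are log2 differences of group means ± SE from limma, group means are given ± SD, and a gene "rose" or "fell" only where its adjusted p passed 0.05. The largest rises and falls are named among the genes that passed and whose compared groups did not overlap in any sample. Levels under the lower quartile of an array (4.495 to 4.711) were taken as near background, so a difference from such a level is at best a lower bound and its rank is open. The p-values use the spread between samples, pooled over all groups of a fit, compared or not. Normal subsets, effusions, HMEC lines and cancer lines came with their own media, handling and sources, so group and source cannot be separated.

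**Figure D1:**
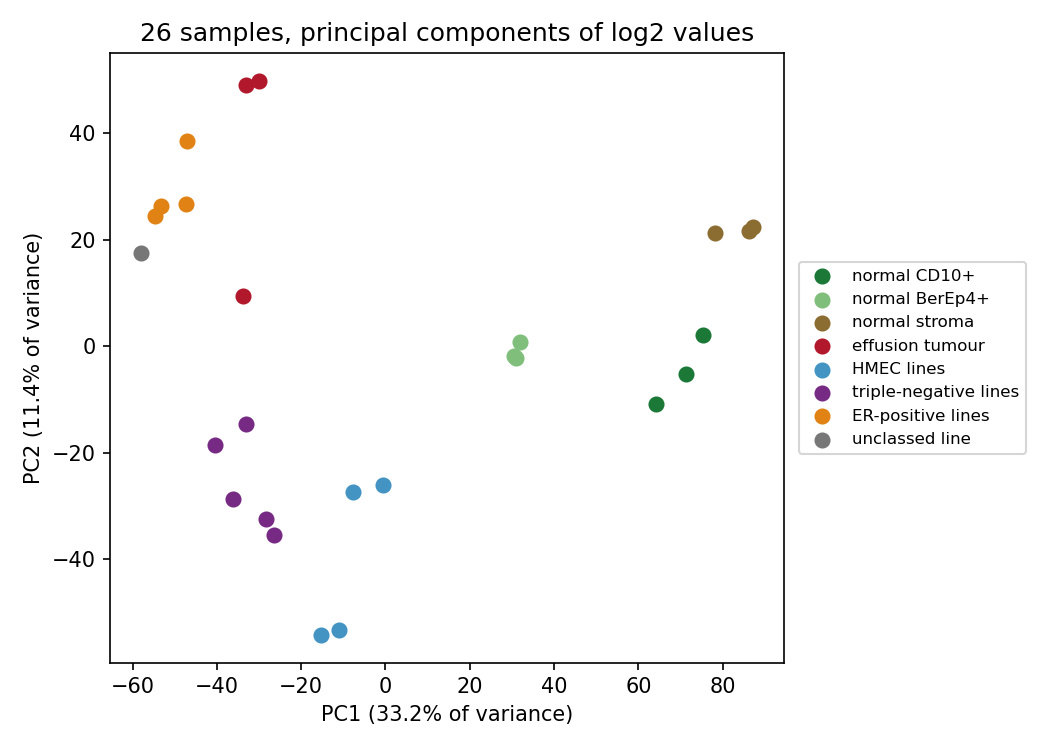
Principal component plot of the 26 samples over 11939 genes, with component 1 (33.2% of the variance) on the horizontal axis and component 2 (11.4%) on the vertical axis; each point is 1 sample coloured by its group. The 9 normal samples lie at positive values of component 1, from 30.5 to 87.3, and the 17 others at negative values.

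The first question was which genes separate the 2 epithelial fractions. CD10 is the product of MME, a surface protease of myoepithelial cells, and BerEp4 recognises the product of EPCAM, a surface protein of epithelial cells. MME was lower in the BerEp4+ fraction (4.19 ± 0.16, n = 3) than in the CD10+ fraction (9.42 ± 0.16, n = 3), a log2 difference of -5.23 ± 0.87 (adjusted p = 5.3e-04). EPCAM measured 10.24 ± 0.39 against 7.14 ± 1.16, a difference of 3.10 ± 1.3 that did not pass (adjusted p = 0.156). In a fit of only the 6 compared samples EPCAM passed (adjusted p = 0.02). The largest rises in the BerEp4+ fraction were in S100A8, a calcium-binding protein of inflammation (6 ± 1.45, adjusted p = 0.0113), OLFM4, a secreted glycoprotein (5.89 ± 0.93, adjusted p = 3.0e-04), and LTF, the milk protein lactoferrin (5.71 ± 0.53, adjusted p = 3.6e-07). The largest falls were in POSTN, the matrix protein periostin (-7.79 ± 1.69, adjusted p = 0.00528), JAM3, a junction protein (-6.59 ± 0.88, adjusted p = 3.7e-05), and GEM, a small GTPase (-6.12 ± 0.91, adjusted p = 1.4e-04). The call of S100A8 was lost without CD10+ replicate 3 (adjusted p = 0.0674). The value of POSTN became 0.02 when probe sets ending in _x_at or _s_at were left out.

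Basal and myoepithelial markers fell in the BerEp4+ fraction. Of 16 measured, 6 fell and none rose (7 fell when adjusted over the list alone; camera adjusted p = 2.2e-06, and adjusted p = 0.177 with an estimated correlation). Besides MME they included ACTA2, smooth muscle actin (-4.98 ± 1.08), OXTR, the oxytocin receptor (-4.88 ± 0.53), and MYLK, myosin light chain kinase (-4.59 ± 0.6). Among 21 luminal markers, 4 rose (8 adjusted over the list alone; camera adjusted p = 2.7e-04, and adjusted p = 0.661 with an estimated correlation). They included MUC1, an apical mucin (3.95 ± 1.23, adjusted p = 0.0479), and CLDN4, a tight junction protein (2.25 ± 0.62, adjusted p = 0.0267). Milk and secretory genes rose in 6 of 13 cases (8 adjusted over the list alone; camera adjusted p = 3.1e-05, and adjusted p = 0.0247 with an estimated correlation). LTF stood first, followed by SLPI, a protease inhibitor of secretions (4.96 ± 1.42, adjusted p = 0.0327), and WFDC2 (3.00 ± 0.93, adjusted p = 0.0477). Of 19 genes of oxidative phosphorylation, 7 rose (12 adjusted over the list alone; camera adjusted p = 6.8e-08, and adjusted p = 0.0247 with an estimated correlation), among them SDHC (2.26 ± 0.43), NDUFV2 (1.94 ± 0.32) and COX5B (1.76 ± 0.29), subunits of respiratory complexes. Fibroblast and matrix genes fell in 4 of 18 cases (4 adjusted over the list alone; camera adjusted p = 0.00116, and adjusted p = 0.555 with an estimated correlation). DCN stood at -3.45 ± 0.37 (adjusted p = 2.6e-06). The calls of MUC1, CLDN4, SLPI and WFDC2 were each lost without any 1 of the 6 libraries except CD10+ replicate 1 (adjusted p from 0.0601 to 0.234). With the donor as a block, MUC1 (adjusted p = 0.0644) and WFDC2 (0.0615) did not pass.

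Genes of cystine uptake and glutathione did not separate the fractions, with none of 17 past the threshold over all genes or over the list alone (median -0.04, mean 0.05, test upward, camera adjusted p = 0.958). SLC7A11, which encodes the cystine-glutamate antiporter xCT, differed by 0.55 ± 1.14 (adjusted p = 0.855). Among 18 genes of glutamine metabolism 2 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.39). These were GMPS, of purine synthesis (1.79 ± 0.55, adjusted p = 0.0472), GOT2, the mitochondrial aspartate aminotransferase (1.67 ± 0.35, adjusted p = 0.00414), and SLC1A5, a glutamine carrier (-1.03 ± 0.26, adjusted p = 0.0163). GMPS was lost without any 1 library except CD10+ replicate 1 (0.0739 to 0.338) and with the donor as a block (0.0542). SLC1A5 was lost without CD10+ replicate 2 or 3 or BerEp4+ replicate 2 (0.0629 to 0.118). Over all genes 563 rose and 434 fell, 997 of 11939, of which 808 had an absolute log2 difference of at least 1. With a repeated quantile normalization 561 rose and 614 fell, and with array weights 1949 passed. The count was 536, 576 and 593 without CD10+ replicate 3, BerEp4+ replicate 2 and CD10+ replicate 2. The difference between the 3-prime and 5-prime GAPDH control probe sets, a measure of RNA quality, was 3.571 ± 2.08 in BerEp4+ and 2.575 ± 1.865 in CD10+ arrays. Without CD10+ replicate 1, the tests of the glycolysis, endothelial and dissociation lists passed (adjusted p from 0.0156 to 0.0417), and without BerEp4+ replicate 1 that of the mesenchymal list did (0.0405).

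Stroma was compared with the 6 epithelial samples to see which cells it held. Fibroblast and matrix genes rose most. Of 18 measured, 15 rose (16 adjusted over the list alone; camera adjusted p = 3.2e-24, and adjusted p = 0.0022 with an estimated correlation). COL3A1, a fibrillar collagen, rose by 7.09 ± 1.49 (adjusted p = 0.00252) and DCN, the matrix proteoglycan decorin, by 5.93 ± 0.7, from 6.62 ± 1.97 (n = 6) to 12.55 ± 0.3 (n = 3). COL3A1 became -0.03 without probe sets ending in _x_at or _s_at. Lymphocyte markers rose in 10 of 17 cases (10 adjusted over the list alone; camera adjusted p = 1.0e-15, and adjusted p = 0.0022 with an estimated correlation). JCHAIN, the joining chain of secreted antibodies, rose by 7.58 ± 0.25 (adjusted p = 7.5e-17), and CD8A, of cytotoxic T cells, rose by 5.37 ± 0.16.

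Markers of other cell types were also higher in stroma. Macrophage genes rose in 5 of 13 cases (8 adjusted over the list alone; camera adjusted p = 1.3e-06, and adjusted p = 0.104 with an estimated correlation), led by LYZ, lysozyme (4.28 ± 0.35), and FCER1G, an Fc receptor chain (3.14 ± 0.39). Endothelial genes rose in 6 of 15 (8 adjusted over the list alone; camera adjusted p = 3.4e-06, and adjusted p = 0.104 with an estimated correlation), led by SELE (5.44 ± 0.46) and PECAM1 (3.69 ± 0.35), adhesion molecules of vessels. Of 18 antigen presentation genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 2.7e-07, and adjusted p = 0.0743 with an estimated correlation), with HLA-DRA at 4.63 ± 0.36 and HLA-DPB1 at 3.67 ± 0.23, both of MHC class II. Mesenchymal genes rose in 6 of 16 (7 adjusted over the list alone; camera adjusted p = 7.4e-07, and adjusted p = 0.132 with an estimated correlation), among them the transcription factor ZEB2 (5.42 ± 0.91) and FN1, fibronectin (4.19 ± 0.92, which became -0.04 without probe sets ending in _x_at or _s_at). Among 13 adipocyte markers 2 rose (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0501), and the test passed in 6 of 9 fits, without any stromal replicate, BerEp4+ replicate 1 or 3, or CD10+ replicate 2 (0.0304 to 0.0479). Of 6 erythrocyte markers 1 rose (median -0.11, mean 0.51, test upward, camera adjusted p = 0.759).

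Inflammatory cytokines rose in 8 of 17 cases (8 adjusted over the list alone; camera adjusted p = 9.0e-06, and adjusted p = 0.0562 with an estimated correlation). IL6 rose by 4.20 ± 0.37, from 8.65 ± 0.77 to 12.85 ± 0.07, and IL1B by 3.71 ± 0.49. Immediate-early genes, which dissociation of tissue can induce, rose in 3 of 17 (7 adjusted over the list alone; camera adjusted p = 1.4e-05, and adjusted p = 0.216 with an estimated correlation). FOS stood at 2.75 ± 0.57 and NR4A2 at 2.11 ± 0.51. Interferon response genes rose in 2 of 19 (2 adjusted over the list alone; camera adjusted p = 0.00181, and adjusted p = 0.585 with an estimated correlation). Basal markers fell in 4 of 16 cases (5 adjusted over the list alone; camera adjusted p = 0.0259, and adjusted p = 0.585 with an estimated correlation). KRT14, a basal keratin, stood at -4.04 ± 1.05 (adjusted p = 0.0142) and SFN at -2.92 ± 0.52 (4.4e-04). The basal call was lost without stroma replicate 1 or any CD10+ replicate (0.0568 to 0.0888), and KRT14 without stroma replicate 1 or 2 (0.0697 to 0.0934). Glycolysis genes fell in 5 of 16 (6 adjusted over the list alone; camera adjusted p = 0.0141, and adjusted p = 0.305 with an estimated correlation), with ALDOA, an enzyme of the pathway, at -1.35 ± 0.32 (0.0077; 0.0525 without stroma replicate 1). The glycolysis call was lost with the median over probe sets (0.067) and without those ending in _x_at or _s_at (0.0607). Of 17 cystine and glutathione genes 1 rose (median -0.14, mean -0.03, test upward, camera adjusted p = 0.701), and SLC7A11 differed by -0.06 ± 0.97 (adjusted p = 0.979). Altogether 653 genes rose and 596 fell, 1249 in all (841 with an absolute log2 difference of at least 1), while the median over all genes was -0.13. More fell (736) than rose (643) with arrays centred on their median. The balance moved too. With array weights 3279 passed (1226 higher, 2053 lower), with the GAPDH 3-prime to 5-prime difference as a covariate 747 (482 and 265), without both normal samples in which it was largest 820 (524 and 296), and without stroma replicate 1 and 2 655 (455 and 200) and 686 (466 and 220). The NRF2 target test passed without BerEp4+ replicate 2 (0.0482). GAPDH 3-prime to 5-prime differences were 1.572 ± 0.059 in stroma and 1.224 to 5.83 in the 6 epithelial arrays.

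HMEC lines were compared with uncultured epithelium. SLC7A11 was higher in HMEC lines (9.59 ± 1.32, n = 4 from 2 laboratories) than in normal epithelium (5.72 ± 0.75, n = 6 from 3 donors). The difference was 3.87 ± 0.89 or 14.6-fold (adjusted p = 0.00416), with lines and fractions taken as independent. With the median over its 3 probe sets the difference was 0.77 and did not pass (adjusted p = 0.27), and the 3 probe sets gave 0.67, 3.87 and 1.8. Of 17 cystine and glutathione genes, 6 rose and 1 fell (7 and 2 adjusted over the list alone), but the list as a whole was not called (camera adjusted p = 0.0958; 0.0311 without 184A1). The risers included GSTP1, a glutathione transferase (2.83 ± 0.99, adjusted p = 0.0495), and GCLC, the catalytic subunit of the first enzyme of glutathione synthesis (1.72 ± 0.57, 0.0397). SLC3A2, the partner chain of xCT, differed by 0.77 ± 0.35 (adjusted p = 0.123; 0.00447 without 184A1) and GCLM, the regulatory subunit paired with GCLC, by -1.25 ± 0.57 (0.121). GSTP1 was lost without any 1 of the 10 libraries (0.0563 to 0.108), and GCLC without HMLE, HMLE-PR, 184B5, CD10+ replicate 1 or 2, or BerEp4+ replicate 3 (0.0577 to 0.107). Amino acid response and serine genes rose in 5 of 19 and fell in 1 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0225, and adjusted p = 0.341 with an estimated correlation). TRIB3, a target of ATF4 (2.56 ± 0.44), PSPH, of serine synthesis (2.45 ± 0.51), and DDIT4, a stress-induced inhibitor of mTORC1 (2.36 ± 0.66), rose, while ATF3 fell (-2.51 ± 0.57). Of 18 genes of glutamine metabolism 1 rose (1 adjusted over the list alone), GFPT1, which uses glutamine to make hexosamines (1.96 ± 0.49). Its list test gave an adjusted p = 0.0303, and an adjusted p = 0.308 with an estimated correlation. Both the amino acid call (0.0634 to 0.0749) and the glutamine call (0.0717 to 0.0873) were lost without HMLE or HMLE-PR, and under 2 (0.0513 to 0.148) and 3 (0.106 to 0.148) other alternatives.

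Squamous differentiation and cell cycle genes rose in HMEC lines. Squamous genes rose in 7 of 18 cases (8 adjusted over the list alone; camera adjusted p = 1.2e-04, and adjusted p = 0.308 with an estimated correlation). SPRR1B, a precursor of the cornified envelope, rose to 9.77 ± 0.35 from 4.19 ± 0.16, a level under the lower quartile of every array, so that the difference of 5.58 ± 0.14 (adjusted p = 1.3e-18) is at best a lower bound. FN1 (5.33 ± 0.84) and the cytokine IL1A (4.94 ± 0.23) were among the largest rises, though without probe sets ending in _x_at or _s_at they became 0.27 and -0.3. Cell cycle genes rose in 11 of 22 (18 adjusted over the list alone; camera adjusted p = 6.5e-09, and adjusted p = 0.308 with an estimated correlation), with the mitotic kinase AURKA at 3.53 ± 0.83 and CDK1 at 3.07 ± 0.76. Oxidative phosphorylation genes rose in 8 of 19 (10 adjusted over the list alone; camera adjusted p = 1.9e-04, and adjusted p = 0.308 with an estimated correlation), led by NDUFB5 (2.11 ± 0.42). Interferon response genes rose in 3 of 19 (5 adjusted over the list alone; camera adjusted p = 0.00954, and adjusted p = 0.464 with an estimated correlation), a call lost without 184B5 (0.21) or the dimmest 25% of genes (0.189). Basal markers rose in 3 of 16 and fell in 1 (3 and 2 adjusted over the list alone; median -0.25, mean -0.18, test upward, camera adjusted p = 0.884). OXTR fell (-3.07 ± 0.91, adjusted p = 0.0216), a call lost without any CD10+ replicate or HMLE-PR (0.0516 to 0.0548).

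Immediate-early genes fell in 11 of 17 cases (11 adjusted over the list alone; camera adjusted p = 6.5e-09, and adjusted p = 0.308 with an estimated correlation). Of 17 inflammatory cytokine genes 3 rose and 7 fell (3 and 11 adjusted over the list alone; camera adjusted p = 0.00936, and adjusted p = 0.308 with an estimated correlation), with IL1A up, CCL2, a monocyte chemokine, at -3.68 ± 0.58 and CXCL3 at -2.55 ± 0.52. Antigen presentation genes fell in 6 of 18 (6 adjusted over the list alone; camera adjusted p = 0.0173, and adjusted p = 0.418 with an estimated correlation), led by CD74, the MHC class II chaperone (-2.96 ± 0.41). That call was lost with the GAPDH 3-prime to 5-prime difference as a covariate (0.0736). Milk genes fell in 3 of 13 (3 adjusted over the list alone; camera adjusted p = 0.0303, and adjusted p = 0.416 with an estimated correlation), with LTF at -4.41 ± 1.03 (0.00488). The milk call was lost without HMLE or BerEp4+ replicate 1 or 2 (0.051 to 0.0769) and under 4 other alternatives (0.0513 to 0.137). The largest falls were in MGP, a calcification inhibitor (-6.48 ± 1.56), CXCR4, a chemokine receptor (-6.26 ± 1.23), and PROM1, the surface protein CD133 (-6.08 ± 1.46). Over all genes 1205 rose and 1014 fell, 2219 in all (1358 with an absolute log2 difference of at least 1), and 1454 without HMLE. With HMEC lines averaged by laboratory, 780 passed (502 rose and 278 fell). More fell than rose with a repeated quantile normalization (1244 and 1026) and with arrays centred on their median (1303 and 1170). Tests of other lists passed without 1 library: cholesterol and fatty acid synthesis without 184A1 (0.0477), fibroblast genes without HMLE-PR (0.0159), glycolysis (0.0428) and mesenchymal genes (0.0408) without 184B5, and lymphocyte genes without 184A1, 184B5 or BerEp4+ replicate 1 or 2 (0.0339 to 0.0485). GAPDH 3-prime to 5-prime differences were 1.515 ± 0.387 in HMEC arrays (1.172 to 1.859) and 1.224 to 5.83 in epithelial arrays.

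Effusion tumour cells were compared with normal epithelium, both uncultured. CD10+ samples in the reference may add to luminal and basal changes. Inflammatory cytokines fell in 14 of 17 (16 adjusted over the list alone; camera adjusted p = 2.8e-15, and adjusted p = 7.0e-04 with an estimated correlation). The neutrophil chemokines CXCL1 (-6.52 ± 0.95), CXCL3 (-6.29 ± 0.57, from 11.21 ± 0.14 to 4.92 ± 0.12), CXCL2 (-6.29 ± 0.51) and CXCL8 (-5.38 ± 0.92) were among them. Immediate-early genes fell in 7 of 17 (8 adjusted over the list alone; camera adjusted p = 6.6e-06, and adjusted p = 0.236 with an estimated correlation). Basal markers fell in 6 of 16 (11 adjusted over the list alone; camera adjusted p = 7.7e-06, and adjusted p = 0.236 with an estimated correlation). CAV1, caveolin, stood at -6.64 ± 1.62 (adjusted p = 0.0062), with KRT14 at -6.25 ± 1.05 and KRT5 at -4.72 ± 1.22. The largest rises were in CGA, the shared subunit of glycoprotein hormones (6.23 ± 0.46, adjusted p = 2.1e-08), SLC2A10, a glucose carrier family member (5.07 ± 1.19), and ESR1, the oestrogen receptor (4.90 ± 1.6, adjusted p = 0.0349). ESR1 became -0.03 with the median over its 9 probe sets, and was lost without any CD10+ replicate or effusion sample 1 or 3 (0.0647 to 0.146).

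Luminal markers rose in 5 of 21 (6 adjusted over the list alone; camera adjusted p = 0.00782, and adjusted p = 0.624 with an estimated correlation). They included ESR1 and KRT19, a luminal keratin (3.83 ± 1.21, adjusted p = 0.0288). Oestrogen response genes rose in 7 of 19 and fell in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0269, and adjusted p = 0.624 with an estimated correlation), with NAT1 at 3.22 ± 0.81 (0.0073). Both list calls were lost without effusion sample 1 (0.0807 and 0.0843), and the latter under 3 other alternatives (0.0548 to 0.103). ERBB2, the HER2 receptor, rose (3.49 ± 0.96, adjusted p = 0.014; 0.131 without effusion sample 1), the 1 of 10 amplicon genes to do so (1 adjusted over the list alone; camera adjusted p = 0.166; 0.0234 to 0.0351 without effusion sample 2 or 3). KRT19 was lost without any CD10+ replicate or any effusion sample (0.0573 to 0.0902) and NAT1 without effusion sample 3 (0.11). Cell cycle genes rose in 9 of 22 (12 adjusted over the list alone; camera adjusted p = 3.8e-06, and adjusted p = 0.533 with an estimated correlation). Oxidative phosphorylation genes rose in 9 of 19 and fell in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 7.7e-06, and adjusted p = 0.236 with an estimated correlation). Fatty acid synthesis genes rose in 3 of 9 (5 adjusted over the list alone; camera adjusted p = 0.0139, and adjusted p = 0.233 with an estimated correlation), including the desaturase SCD (2.20 ± 0.56, adjusted p = 0.00783). The list and SCD were lost without effusion sample 1 (0.059 and 0.0831), and the list under 2 other alternatives (0.0872 to 0.147). Cholesterol synthesis genes rose in 4 of 13 (5 adjusted over the list alone; camera adjusted p = 0.0425, and adjusted p = 0.533 with an estimated correlation). FDPS stood at 1.92 ± 0.39. That list was lost without effusion sample 1 or 2 or CD10+ replicate 2 (0.0611 to 0.0981) and under 5 other alternatives (0.0555 to 0.172).

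Of the 17 cystine and glutathione genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.97). GCLM had the largest fall, 3.15 ± 0.62 (adjusted p = 0.00122), from 7.96 ± 0.58 to 4.81 ± 0.27, and SLC3A2 differed by -1.19 ± 0.38 (adjusted p = 0.0331). SLC7A11 did not pass (-0.16 ± 0.97, adjusted p = 0.93). GGCT, of glutathione breakdown, rose (1.71 ± 0.41, adjusted p = 0.00563). SLC3A2 was lost without any CD10+ replicate or any effusion sample (0.0577 to 0.0916), and GGCT without effusion sample 2 (0.0528). Among 18 glutamine genes 1 rose (1 adjusted over the list alone; camera adjusted p = 0.391), and among 15 hypoxia genes 1 rose and 2 fell (camera adjusted p = 0.356). Macrophage markers rose in 6 of 13 cases (7 adjusted over the list alone; camera adjusted p = 1.3e-04, and adjusted p = 0.236 with an estimated correlation), with LYZ at 4.09 ± 0.35 and FCER1G at 2.05 ± 0.39. The macrophage call was lost when the dimmest 25% of genes were left out (0.103). Fibroblast genes fell in 3 of 18 (3 adjusted over the list alone; camera adjusted p = 0.0425, and adjusted p = 0.624 with an estimated correlation). Milk genes fell in 2 of 13 (2 adjusted over the list alone; camera adjusted p = 0.0462, and adjusted p = 0.533 with an estimated correlation). Mesothelial markers fell in 1 of 10 (1 adjusted over the list alone; camera adjusted p = 0.0425, and adjusted p = 0.233 with an estimated correlation), and that 1 was KRT5, also a basal keratin. The fibroblast call was lost without effusion sample 1 or 2 or CD10+ replicate 1 or 3 (0.0558 to 0.102), the milk call without any effusion sample or any BerEp4+ replicate (0.0577 to 0.121), and the mesothelial call without effusion sample 1 or 2, BerEp4+ replicate 3 or CD10+ replicate 3 (0.0577 to 0.0757). Under other alternatives they were lost 4 (0.0548 to 0.238), 7 (0.0557 to 0.162) and 6 times (0.0542 to 0.103). In all, 1243 genes rose and 973 fell, 2216 together (1595 with an absolute log2 difference of at least 1), and 1455 without effusion sample 3. With a repeated quantile normalization 1118 rose and 1150 fell, and in a fit of only the compared samples 1403 passed. Tests of further lists passed without 1 library, amino acid response without CD10+ replicate 2 (0.047), interferon response without effusion sample 1 (0.0144) and squamous genes without effusion sample 2 (0.0351). The GAPDH 3-prime to 5-prime difference was 1.327 ± 0.389 in effusion arrays and 1.224 to 5.83 in epithelial arrays.

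All 10 cancer lines were compared with the 4 HMEC lines. Squamous, basal and cytokine genes fell. Squamous genes fell in 10 of 18 cases (13 adjusted over the list alone; camera adjusted p = 3.5e-18, and adjusted p = 0.00233 with an estimated correlation). SPRR1B was at -5.83 ± 0.13 (3.94 ± 0.11, n = 10, against 9.77 ± 0.35, n = 4) and DSC3, a desmosomal cadherin, at -5.61 ± 0.58. Inflammatory cytokines fell in 10 of 17 (12 adjusted over the list alone; camera adjusted p = 1.3e-18, and adjusted p = 1.9e-04 with an estimated correlation). PTGS2, the inducible cyclooxygenase, stood at -6.56 ± 0.54 (adjusted p = 2.9e-08). Basal markers fell in 7 of 16 (10 adjusted over the list alone; camera adjusted p = 5.9e-09, and adjusted p = 0.111 with an estimated correlation), with KRT14 at -5.23 ± 0.88, LAMB3, a laminin chain, at -4.68 ± 0.66 and EGFR, the epidermal growth factor receptor, at -2.50 ± 0.69 (adjusted p = 0.0304). EGFR became 0.02 without probe sets ending in _x_at or _s_at and was lost without any 1 HMEC line (0.0508 to 0.123). Mesenchymal genes fell in 3 of 16 (3 adjusted over the list alone; camera adjusted p = 3.3e-05, and adjusted p = 0.259 with an estimated correlation). FN1 stood at -3.61 ± 0.77. The largest rises were in MYB, a transcription factor (3.44 ± 0.54, adjusted p = 3.7e-04), BAMBI, a pseudoreceptor of TGF-beta signalling (3.09 ± 0.69, 0.00801), and PCLAF, a PCNA-binding protein (2.87 ± 0.51, 0.00138).

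Amino acid response and serine genes fell in 4 of 19 cases (9 adjusted over the list alone; camera adjusted p = 1.4e-08, and adjusted p = 0.0137 with an estimated correlation). The 4 were DDIT4 (-2.45 ± 0.6, adjusted p = 0.0166), TRIB3 (-1.68 ± 0.4, 0.0132), CHAC1, which degrades glutathione (-1.32 ± 0.29, 0.00655), and DDIT3, the transcription factor CHOP (-1.10 ± 0.25, 0.0104). TRIB3 and DDIT3 were lost without HMLE or HMLE-PR (0.0518 to 0.0817), and DDIT4 without 184B5 (0.0509). ASNS, asparagine synthetase, measured -1.46 ± 0.59 (adjusted p = 0.162). Of 17 cystine and glutathione genes 1 rose and 2 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.128; 0.025 without 184A1). GSTP1 (-3.47 ± 0.91, adjusted p = 0.0237) and SLC3A2 (-1.62 ± 0.32, adjusted p = 0.00324) fell, SLC3A2 from 9.69 ± 1.19 to 8.07 ± 0.37, and GGCT rose (1.18 ± 0.35, 0.0429). SLC7A11 measured 7.47 ± 1.9 against 9.59 ± 1.32, a difference of -2.12 ± 0.81 that did not pass (adjusted p = 0.139; 0.0447 without MDA-MB-231). GSTP1 was lost without HMLE, 184A1 or 184B5 (0.0595 to 0.0803), and GGCT without any library except 184B5, BT549, HCC3153 and MDA-MB-231 (0.0513 to 0.24). Among 18 glutamine genes 1 fell (1 adjusted over the list alone; camera adjusted p = 0.157), SLC38A2, a sodium-coupled carrier of glutamine (-0.96 ± 0.24, adjusted p = 0.0176), which was lost without HMLE-PR or 184A1 (0.0517 to 0.0539). SLC7A5, the large neutral amino acid carrier, measured -1.61 ± 0.53 (adjusted p = 0.0792; 0.0472 without T74D).

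Cell cycle genes rose in 10 of 22 cases (20 adjusted over the list alone; camera adjusted p = 5.8e-13, and adjusted p = 0.2 with an estimated correlation). Oxidative phosphorylation genes rose in 2 of 19 (5 adjusted over the list alone; camera adjusted p = 9.7e-05, and adjusted p = 0.259 with an estimated correlation). These were the respiratory subunits NDUFS3 (0.81 ± 0.23, adjusted p = 0.0407) and SDHA (0.72 ± 0.22, adjusted p = 0.0486). NDUFS3 was lost without any HMEC line, HCC1187, HCC3153, BT549, MCF7, BT474 or T74D (0.0532 to 0.139), and SDHA without any library except ZR_75-30 and MDA-MB-231 (0.0517 to 0.167). Immediate-early genes fell in 1 of 17 (7 adjusted over the list alone; camera adjusted p = 8.4e-05, and adjusted p = 0.259 with an estimated correlation). Hypoxia genes fell in 2 of 15 (6 adjusted over the list alone; camera adjusted p = 5.7e-04, and adjusted p = 0.174 with an estimated correlation), ANGPTL4 (-2.36 ± 0.49) and the growth factor VEGFA (-1.79 ± 0.38). The hypoxia call was lost without probe sets ending in _x_at or _s_at (0.188). No interferon response gene of 19 passed (median -0.65; camera adjusted p = 6.1e-04, and adjusted p = 0.434 with an estimated correlation), nor any of 18 antigen presentation genes (median -0.37; camera adjusted p = 0.0299, and adjusted p = 0.434 with an estimated correlation). The interferon call was lost without 184B5 (0.38), and the antigen presentation call without 184B5, MCF7 or BT474 (0.0567 to 0.0809) or probe sets ending in _x_at or _s_at (0.311). The luminal test passed without HCC1187, HCC3153, BT549 or MDA-MB-231 (0.00236 to 0.0396), and the cholesterol test without HMLE-PR, HCC3153 or BT549 (0.0396 to 0.0499). In total 314 genes rose and 400 fell, 714 together (505 with an absolute log2 difference of at least 1), against 473, 458 and 435 without HMLE, 184A1 and 184B5. With HMEC lines averaged by laboratory 39 rose and 124 fell, 163 together. The count was 436 without probe sets ending in _x_at or _s_at and 457 in a fit of only the compared samples.

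Uncultured effusion tumours were set against cancer lines. The largest rises in effusion samples were in TCIM, a regulator of Wnt signalling (7.18 ± 0.88, adjusted p = 6.9e-05), CGA (6.37 ± 0.42, adjusted p = 3.0e-09) and LYZ (4.59 ± 0.32, adjusted p = 5.1e-09). Macrophage markers rose in 6 of 13 cases and none fell (10 rose adjusted over the list alone; camera adjusted p = 7.0e-19, and adjusted p = 0.00678 with an estimated correlation). They included LYZ, FCER1G at 2.58 ± 0.36, TYROBP, a signalling adaptor of myeloid cells, at 1.53 ± 0.27 (adjusted p = 0.00605), and CSF1R, the receptor of a macrophage growth factor, at 1.06 ± 0.22 (adjusted p = 0.0227). TYROBP was lost without effusion sample 3 (0.0895) and CSF1R without effusion sample 2 or 3 (0.0668 to 0.117). Antigen presentation genes rose in 4 of 18 (6 adjusted over the list alone; camera adjusted p = 2.6e-08, and adjusted p = 0.0988 with an estimated correlation). All were of MHC class II or its chaperone: CD74 (3.07 ± 0.41), HLA-DRA (2.69 ± 0.33), HLA-DPB1 (2.68 ± 0.22) and HLA-DRB1 (1.73 ± 0.32, adjusted p = 0.0101; 0.0668 without effusion sample 3). No lymphocyte marker of 17 passed (median -0.03, mean 0, test downward, camera adjusted p = 0.942), nor any mesothelial marker of 10 (median -0.05, camera adjusted p = 0.798), and 1 of 15 endothelial markers rose (median -0.01, mean 0.06, test upward, camera adjusted p = 0.798).

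Cell cycle genes were lower in effusion samples. Of 22, 3 fell (16 adjusted over the list alone; camera adjusted p = 7.0e-19, and adjusted p = 0.108 with an estimated correlation). These were the cyclin CCNB2 (-2.71 ± 0.58, adjusted p = 0.0264), the spindle protein TPX2 (-2.54 ± 0.57, 0.0316) and CDC20, an activator of the anaphase-promoting complex (-1.73 ± 0.4, 0.0361). CCNB2 was lost without effusion sample 1 or 3 (0.0843 to 0.193), TPX2 without effusion sample 1 or 3, HCC3153 or BT549 (0.0527 to 0.196), and CDC20 without effusion sample 1 or 3, HCC3153, BT20, BT549 or MDA-MB-231 (0.0541 to 0.178). Of 17 immediate-early genes 1 rose (8 adjusted over the list alone; camera adjusted p = 5.0e-10, and adjusted p = 0.0988 with an estimated correlation). That gene was the nuclear receptor NR4A2 (2.48 ± 0.47, adjusted p = 0.0121; 0.064 to 0.101 without effusion sample 1 or 3), and FOSB measured 1.89 (adjusted p = 0.088; 4.1e-04 without effusion sample 2). Oestrogen response genes had a median of 1.22 with none of 19 past the threshold (1 adjusted over the list alone; camera adjusted p = 1.8e-04, and adjusted p = 0.513 with an estimated correlation). ESR1 measured 3.25 ± 1.49 (adjusted p = 0.376). Luminal genes had a median of 1.02 with none of 21 past it (0 adjusted over the list alone; camera adjusted p = 9.0e-04, and adjusted p = 0.657 with an estimated correlation), a call lost without effusion sample 1 (0.134). The lines pool receptor classes that differ in both lists: ESR1 measured 11.18 ± 1.32 in effusion samples, 10.84 ± 0.94 in receptor-positive and 5.01 ± 1.17 in triple-negative lines, so these differences may come from the mix of classes, untested. Interferon genes (none of 19; median 0.19; camera adjusted p = 0.0369, and adjusted p = 0.657 with an estimated correlation) lost their call without MCF7, ZR_75-30, BT474, BT549, T74D or effusion sample 2 (0.0549 to 0.801) and under 2 other alternatives (0.0502 to 0.114). NRF2 target genes had a median of -0.41, with none of 17 past the threshold (1 up and 2 down adjusted over the list alone; camera adjusted p = 0.0493, and adjusted p = 0.657 with an estimated correlation). Their call was lost without MCF7, ZR_75-30, HCC3153, BT20 or any effusion sample (0.0652 to 0.293) and under 5 other alternatives (0.0502 to 0.177).

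None of 17 cystine and glutathione genes and none of 18 glutamine genes passed between effusion samples and lines (1 of each fell adjusted over the list alone). SLC7A11 measured -1.91 ± 0.9 (adjusted p = 0.4) and GCLM -1.57 ± 0.58 (adjusted p = 0.217). Over all genes 55 rose and 47 fell, 102 together (87 with an absolute log2 difference of at least 1). The count was 232 without effusion sample 2, 209 without ZR_75-30 and 37 without effusion sample 3, and 46 to 56 under 3 other alternatives. The test of the ERBB2 amplicon passed without ZR_75-30, BT474 or effusion sample 2 or 3 (adjusted p from 0.00106 to 0.0416) and that of hypoxia without effusion sample 2 or 3 (0.0307 to 0.0414). Those of 2 further lists passed without 1 sample, oxidative phosphorylation without BT483, HCC1187, BT20, MDA-MB-231 or effusion sample 2 or 3 (0.0239 to 0.0476), and squamous genes without BT483, HCC1187, HCC3153, BT20 or effusion sample 1 or 3 (3.3e-04 to 0.0485).

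The series is about glutamine sensitivity and the xCT antiporter in triple-negative cancer, so triple-negative lines were compared with oestrogen receptor-positive lines. SLC7A11 measured 8.07 ± 2.28 (n = 5) in triple-negative and 7.29 ± 1.27 (n = 4) in receptor-positive lines. The difference of 0.78 ± 1.16 was smaller than the spread between lines (limma adjusted p = 0.849; exact permutation test over 126 splits, two-sided, p = 0.548). Single triple-negative lines measured 10.62 (MDA-MB-231), 10.34 (BT20), 7.17 (BT549), 6.64 (HCC3153) and 5.55 (HCC1187), and receptor-positive lines from 5.72 to 8.77. The 3 probe sets of SLC7A11 gave 0.78, 0.74 and 0.44, and leaving out 1 line gave 0.14 without MDA-MB-231 and 1.4 without HCC1187. None of 17 cystine and glutathione genes passed over all genes or over the list alone (median 0.3, camera adjusted p = 0.71). SLC3A2 measured 0.37 ± 0.18 (adjusted p = 0.45) and GCLM 1.80 ± 0.5 (7.35 ± 0.75 against 5.55 ± 0.9, adjusted p = 0.159). In the exact permutation test, GCLM had p = 0.0397 (adjusted p = 0.162 over 17 fixed genes). ESR1, at the smallest p these splits can give (0.00794), had an adjusted p = 0.135, so 1 gene alone could not pass after this adjustment. None of 18 glutamine genes passed over all genes or over the list alone (median 0.12, mean -0.15, test upward, camera adjusted p = 0.71). GLUL, glutamine synthetase, measured 8.4 ± 3.12 against 11.78 ± 0.92, a difference of -3.37 ± 1.48 (adjusted p = 0.383; exact permutation p = 0.0794, adjusted 0.193), with HCC3153 at 5.17 and BT549 at 4.92 and the other 3 triple-negative lines from 10.1 to 11.55. SLC1A5 measured -0.55 ± 0.2 (adjusted p = 0.282; exact permutation p = 0.0317, adjusted 0.162). SLC7A5 (0.62), ASNS (0.29), GCLC (-0.96), PHGDH (1.09) and MYC (-0.08) did not pass. GLS and GLS2, the glutaminases, were not analysed here.

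**Figure D2:**
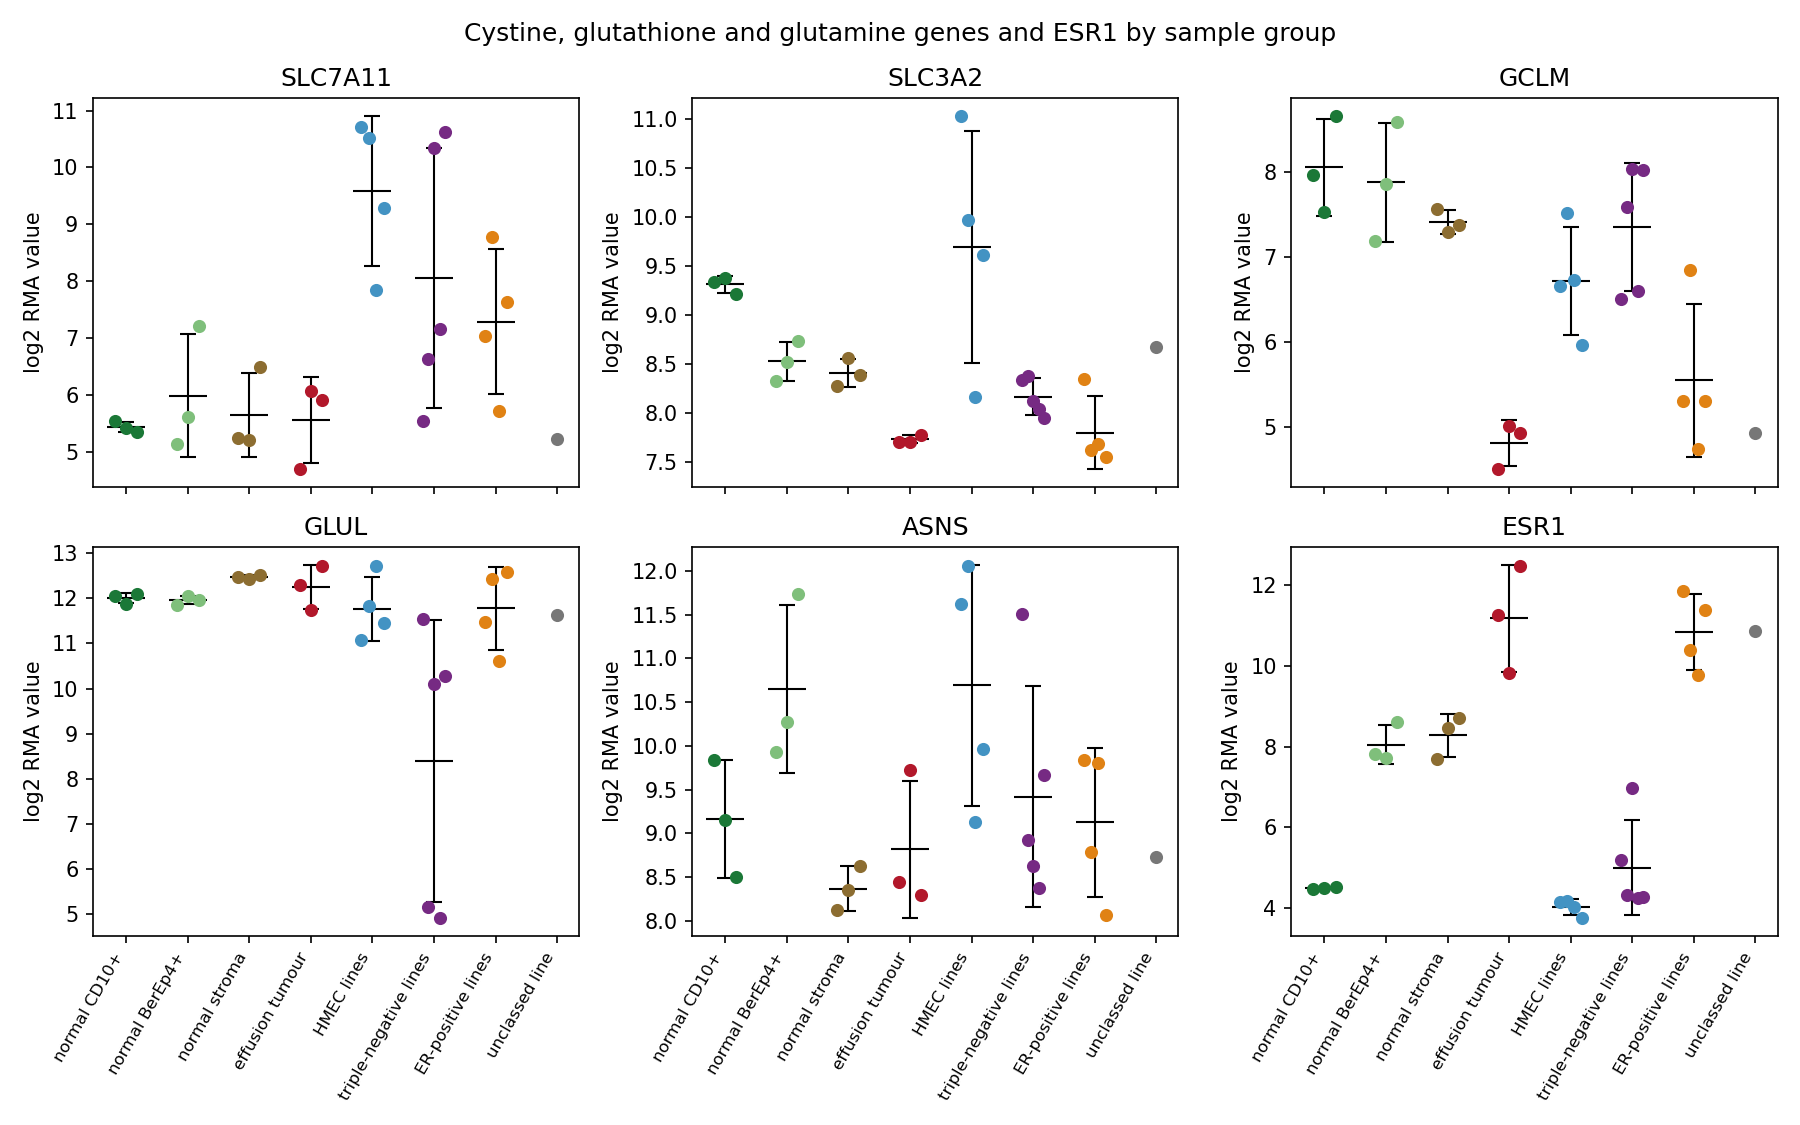
Expression of 6 genes (SLC7A11, SLC3A2, GCLM, GLUL, ASNS and ESR1) as log2 RMA values on the vertical axis, by the 8 groups on the horizontal axis; points are samples and bars the group mean ± SD. SLC7A11 ranged from 5.55 to 10.62 in triple-negative and from 5.72 to 8.77 in oestrogen receptor-positive lines.

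Luminal and oestrogen response genes separated the classes. Oestrogen response genes fell in triple-negative lines in 5 of 19 cases (9 adjusted over the list alone; camera adjusted p = 3.5e-13, and adjusted p = 0.076 with an estimated correlation). TFF1, trefoil factor, had the largest fall (-6.82 ± 0.37, from 11.84 ± 0.85 to 5.02 ± 0.32, adjusted p = 1.5e-04), with ESR1 at -5.84 ± 0.66 (adjusted p = 0.0101) and GREB1, an oestrogen receptor cofactor, at -5.43 ± 0.44 (adjusted p = 0.00215). The other 8 probe sets of ESR1 gave -0.26 to 0.03, and with the median over probe sets neither ESR1 (-0.14) nor GREB1 (-0.48) passed. Luminal markers fell in 5 of 21 (11 adjusted over the list alone; camera adjusted p = 7.3e-13, and adjusted p = 0.123 with an estimated correlation). They were led by AGR2, a secretory pathway protein (-5.86 ± 0.79, adjusted p = 0.0204), ESR1 and the transcription factor XBP1 (-3.21 ± 0.31). The largest rises were in CAV1 (6.41 ± 0.79, adjusted p = 0.0134), MSN, the cytoskeletal linker moesin (6.05 ± 0.17, from 4.26 ± 0.07 to 10.31 ± 0.34, adjusted p = 1.7e-06), and CAV2 (4.95 ± 0.83, adjusted p = 0.0406). AGR2 was lost without HCC3153, ZR_75-30, BT474 or BT483 (0.0533 to 0.0684), and CAV2 without any line except HCC1187 (0.0724 to 0.108). CAV1 was the 1 basal marker of 16 that rose (2 adjusted over the list alone; camera adjusted p = 9.2e-04, and adjusted p = 0.314 with an estimated correlation), while KRT5 measured 2.98 (adjusted p = 0.306). Cell cycle genes rose in 1 of 22 (11 adjusted over the list alone; camera adjusted p = 7.5e-13, and adjusted p = 0.158 with an estimated correlation), CDC20 (1.38 ± 0.23, adjusted p = 0.0406), which was lost without any line except BT20 and BT474 (0.0545 to 0.105).

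Mesenchymal genes had a median difference of 2.19, with none of 16 past the threshold over all genes (3 adjusted over the list alone; camera adjusted p = 1.2e-05, and adjusted p = 0.24 with an estimated correlation). VIM, vimentin, measured 4.36 ± 1.13 (adjusted p = 0.134; 0.0142 without BT20). Inflammatory cytokines had a median of 0.71 and none of 17 past it (3 adjusted over the list alone; camera adjusted p = 2.7e-04, and adjusted p = 0.123 with an estimated correlation). CXCL8 measured 3.12 (adjusted p = 0.0575; 0.03 without HCC1187). The fibroblast list (none of 18; median 0.75) and the cholesterol list (none of 13, 1 fallen adjusted over the list alone; median -0.29) had camera adjusted p = 0.0439 each, and adjusted p = 0.677 and adjusted p = 0.619 with an estimated correlation. Without 1 of 6 lines each the calls were lost, fibroblast genes without MCF7, ZR_75-30, BT474, BT483, HCC1187 or BT549 (0.0634 to 0.175; 0.0734 to 0.453 under 5 other alternatives) and cholesterol genes without MCF7, ZR_75-30, BT474, HCC3153, BT549 or MDA-MB-231 (0.0505 to 0.145; 0.0509 to 0.363 under 5 others). The ERBB2 amplicon (none of 10; median -0.66) had a camera adjusted p = 0.0439, and adjusted p = 0.695 with an estimated correlation, and was lost without ZR_75-30, BT474, HCC1187, HCC3153, BT20 or BT549 (0.0503 to 0.547) and under 7 other alternatives (0.0515 to 0.91). ERBB2 itself measured -2.43 ± 0.97 (adjusted p = 0.332). NRF2 target genes had a median of 0.45 with none of 17 past the threshold (camera adjusted p = 0.0686), and their test passed without MCF7, ZR_75-30, HCC1187, BT549 or MDA-MB-231 (0.00515 to 0.0426). Over all genes 35 rose and 53 fell, 88 together (78 with an absolute log2 difference of at least 1). Without both HER2-amplified lines 2 rose and 31 fell, and CAV1, CAV2 and AGR2 did not pass. The count was 401 in a fit of all 26 samples, 206 with array weights, 157 with the GAPDH covariate, 36 without HCC3153, 39 without ZR_75-30, 49 without MDA-MB-231, 55 without BT483 and 56 without BT474.

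The last comparison asked whether tumour and non-tumour cells differ alike in culture (cancer lines minus HMEC lines) and without culture (effusion tumours minus normal epithelium), as the difference of both differences. Positive values mean a higher value of tumour minus normal in culture. The largest positive values were in PROM1 (8.21 ± 2.09, adjusted p = 0.0212), ID4, an inhibitor of transcription factors (7.63 ± 1.87, 0.0179), and SYNM, an intermediate filament protein (6.33 ± 1.21, 0.00366). The largest negative values were in FN1 (-7.90 ± 1.19, adjusted p = 4.2e-04), S100P (-6.99 ± 2.01, 0.0403) and CGA (-6.20 ± 0.59, 1.1e-06). ID4 was lost without effusion sample 1 or 3 (0.0577 to 0.0755), and S100P without any CD10+ replicate, effusion sample 1 or 2, MCF7, MDA-MB-231, 184A1 or 184B5 (0.0504 to 0.118). Squamous genes had lower values in 5 of 18 cases (7 adjusted over the list alone; camera adjusted p = 2.5e-06, and adjusted p = 0.362 with an estimated correlation), with SPRR1B at -5.74 ± 0.2 and SPRR3 at -5.69 ± 1.14. Macrophage genes had lower values in 3 of 13 (6 adjusted over the list alone; camera adjusted p = 2.0e-04, and adjusted p = 0.671 with an estimated correlation). LYZ stood at -4.09 ± 0.45, and the list lost its call when the dimmest 25% of genes were left out (0.143). Interferon genes had 1 lower of 19 (4 adjusted over the list alone; camera adjusted p = 3.8e-04, and adjusted p = 0.708 with an estimated correlation). Inflammatory cytokines had 6 higher and 2 lower of 17 (6 and 2 adjusted over the list alone; camera adjusted p = 0.0738), with CCL2 at 3.80 ± 0.83, the cytokine LIF at 3.09 ± 0.69 and IL1A at -4.84 ± 0.33. IL1A became 0.27 and FN1 -0.54 without probe sets ending in _x_at or _s_at, and neither passed.

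Among 17 cystine and glutathione genes 2 differed between the settings, GCLM (2.83 ± 0.81, adjusted p = 0.0386) and TXN, thioredoxin (1.53 ± 0.37, adjusted p = 0.0156), both higher (2 adjusted over the list alone; camera adjusted p = 0.326). SLC7A11 measured -1.96 ± 1.27 (adjusted p = 0.373). Of 18 glutamine genes 1 differed (1 adjusted over the list alone; camera adjusted p = 0.121), GFPT1 (-2.64 ± 0.7, adjusted p = 0.0266). GCLM was lost without CD10+ replicate 1 or 3, BerEp4+ replicate 3, any effusion sample, HMLE, 184A1 or 184B5 (0.0532 to 0.0856), TXN without effusion sample 3 (0.0562), and GFPT1 without effusion sample 1, HMLE or 184B5 (0.0508 to 0.0821). Altogether 307 genes had higher and 427 lower values, 734 in all (632 with an absolute log2 difference of at least 1), and 435 without effusion sample 3. With HMEC lines averaged by laboratory 289 passed, without probe sets ending in _x_at or _s_at 481, and with a repeated quantile normalization 370 were higher and 357 lower. Some list tests passed only without 1 library: amino acid response without 184A1 (0.0308), antigen presentation without effusion sample 1 (0.0433), fibroblast genes without HMLE-PR (0.0236) and cytokines without HMLE-PR or T74D (0.0162 to 0.0479). So did immediate-early genes without 184A1, T74D, effusion sample 1 or BerEp4+ replicate 3 (1.5e-04 to 0.0408), and oxidative phosphorylation without 184A1, T74D, effusion sample 1 or any BerEp4+ replicate (0.0295 to 0.0479).

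**Figure D3:**
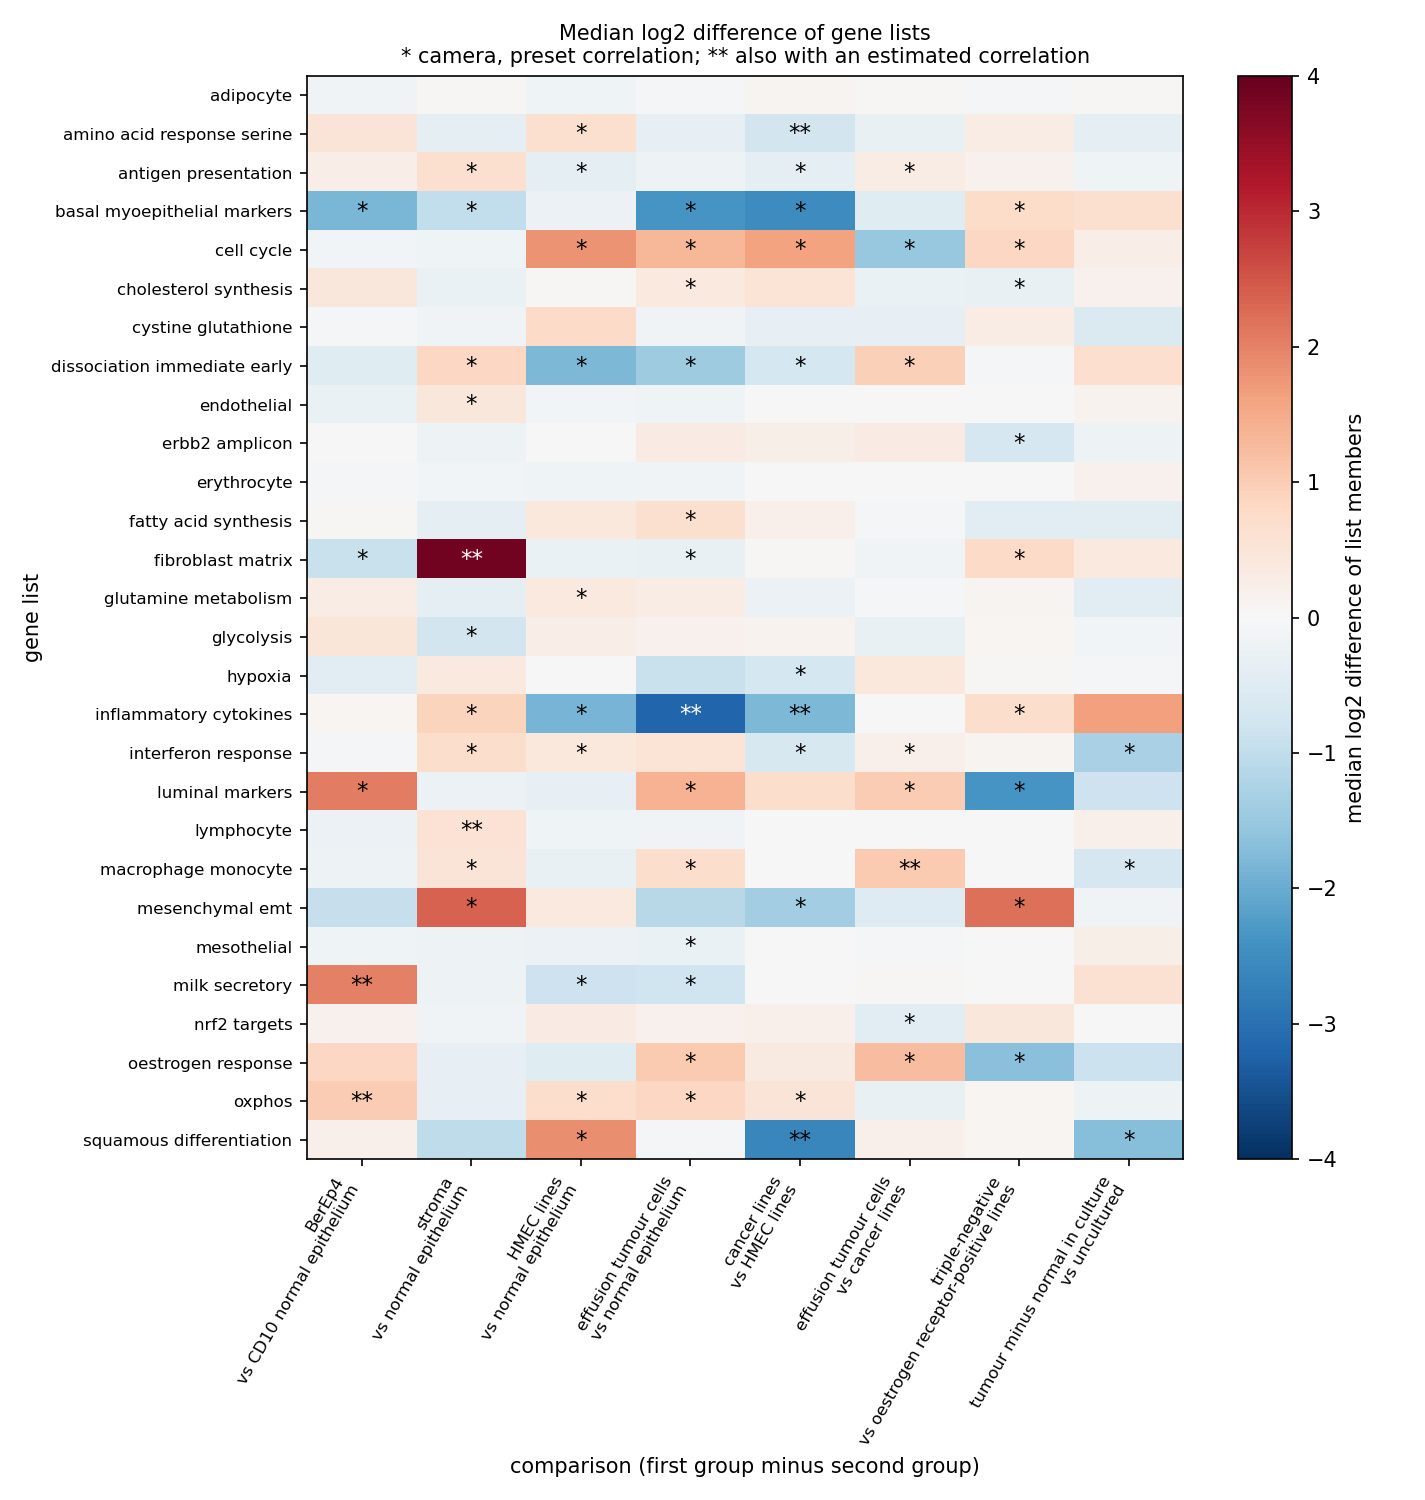
Heat map of the median log2 difference of 28 gene lists (vertical axis) in the 8 comparisons (horizontal axis), with the colour scale in log2 units; 1 star marks a camera adjusted p that passed 0.05 with the preset correlation and a double star a call that also held with an estimated correlation. Inflammatory cytokines had medians of -3.18 in effusion tumours against epithelium and -1.79 in cancer lines against HMEC lines, both with a double star.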

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

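The tests for other cell types, for tissue dissociation, for HMLE with HMLE-PR and for the growth medium were chosen only after the results were seen, as were the RNA quality covariate and the splits by donor and laboratory, while what the covariate and the splits of the samples would have to show was set down before their results were seen.

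Inflammatory cytokine genes were lower in effusion tumour cells than in normal epithelium, 14 of 17 past the threshold and none higher. Carry-over of the stromal fraction as a whole into the epithelial fractions, and RNA quality of the normal samples, are argued against as the whole cause. For these 14 genes epithelium had a median of 62.9% of the stromal level (5.45% to 225%). The 10 genes selected as rising most in stroma had 1.64%. With the GAPDH 3-prime to 5-prime difference as a covariate 11 of the 14 passed, the median going from -3.83 to -3.53. Tissue dissociation of the normal samples may have induced these genes and stays open. HMEC lines, which were not dissociated, differed from epithelium by a median of -1.98 over the 14 genes. Single genes ranged from -3.68 to 2.26, so not all were lower. Culture and dissociation cannot be told apart in this design. A lower cytokine level in the tumour cells themselves stays open, untested.

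Macrophage and MHC class II genes were higher in effusion tumour cells than in cancer lines. Lymphocytes among the effusion cells are argued against (0 of 17 markers above all 10 lines in 2 or 3 effusion samples). Mesothelial cells stay open: 0 of 10 markers did so, but lines reach 10.63 in 1 of them, KRT5. Macrophages and, untested, expression by tumour cells stay open too, since the 8 of 13 macrophage markers that met this only repeat the pattern. LYZ measured 7.59 to 9.11 in effusion samples (3.47 to 4.12 in lines, 8.54 ± 0.98 in stroma), TYROBP 5.8 to 7.84 (5.3 to 5.86 and 6.78 ± 0.34), CSF1R 4.59 to 5.81 (3.75 to 5.09 and 4.39 ± 0.11) and HLA-DRA 6.89 to 8.12 (4.65 to 6.17 and 10.52 ± 0.52). Macrophage removal by cluster filtering was not tested. The general leukocyte gene PTPRC measured 4.43 to 4.65 (4.22 to 4.48 and 8.33 ± 0.6), while EPCAM measured 9.74 to 10.01.

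SLC7A11 was higher in HMEC lines than in normal epithelium, by 3.87. A rise in HMLE and HMLE-PR alone is argued against, since 184A1 and 184B5 together lay 2.85 higher than epithelium, with the lower of them at 7.84 and the highest epithelial sample at 7.21. RNA quality of the normal samples is argued against as the whole cause, since the gene passed with the covariate (4.14 ± 1.03, adjusted p = 0.00932; over all alternatives SLC7A11 had adjusted p from 0.00181 to 0.27, the highest with the median over probe sets). The HMEC growth medium may contribute and stays open, as does growth in culture: cancer lines, in other media, differed from HMEC lines by -2.12, but medium and cell type cannot be told apart. A difference that comes with immortalization stays open, untested.

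Other splits of the same samples were compared with the real ones. Chance can be excluded for stroma (1249 genes; highest other split 1185) and triple-negative against receptor-positive lines (88; 9), where 1 split, the real one, reached the count. With the epithelial fractions averaged per donor and HMEC lines by laboratory, chance can also be excluded for cancer against HMEC lines (219, highest other of 66 splits 96). It is argued against for the last comparison, where 2 of 100 splits, the real one with 463 genes and another with 832, reached the count. Why 832 passed was not tested. For HMEC lines against epithelium the 10 such splits are too few for a share under 0.05 (814; highest other 13), and splits of 4 single lines leave out the laboratories (1691 and 621 by donor). Such splits gave 714 and 256 for cancer against HMEC lines and, by donor, 806 and 139 for the last comparison, where all group labels were again mixed. For effusion tumours against epithelium the 10 splits by donor are too few as well (1883; highest other 1), and the splits of the fractions as separate samples (2216; 1887) leave out the donors. For effusion tumours against cancer lines 5 of 100 splits gave at least the real count of 102, so chance could not be excluded. The highest other gave 390 genes, cause untested. For BerEp4+ against CD10+ epithelium (997; highest other 6) the 10 splits are too few too.

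A sample far from the others of its group was found in 11 of 85 tests of single genes, and chance gives about 1 in 20. In HMEC lines these were PGR at 3.79 in HMLE-PR (others 4.16 to 4.23) and KRT5 at 6.55 in 184A1 (10.33 to 10.79). In triple-negative lines they were SLC7A5 at 8.93 (9.86 to 10.21) and MME at 6.28 (3.75 to 4.47), both in BT549. In receptor-positive lines MCF7 stood apart in SLC3A2 at 8.35 (7.55 to 7.68), MME at 7.73 (3.88 to 4.31) and EPCAM at 10.47 (9.8 to 9.91), and BT474 in MYC at 6.96 (7.72 to 7.81) and VIM at 5.31 (5.03 to 5.06). Over all 10 cancer lines ASNS was 11.51 in HCC1187 (8.07 to 9.84). In normal epithelium SLC7A11 was 7.21 in BerEp4+ replicate 3 (5.14 to 5.62), an array with a GAPDH 3-prime to 5-prime difference of 5.83.

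Some genes past the threshold in the last comparison, which mixes culture with receptor class, are given with tumour minus normal in culture and without. Higher in culture were PROM1 (8.21; 2.04 and -6.17), ID4 (7.63; 3.42 and -4.21), SYNM (6.33; 2.74 and -3.59), MMP3 (5.61; 0.63 and -4.98), COL6A1 (4.63; -0.08 and -4.71), CCL2 (3.80; 0.62 and -3.18), LIF (3.09; -1.79 and -4.88), GCLM (2.83; -0.32 and -3.15), IL6 (2.23; -0.76 and -2.99) and TXN (1.53; 0.64 and -0.89). Lower were FN1 (-7.90; -3.61 and 4.3), S100P (-6.99; -2.91 and 4.08), CGA (-6.20; 0.03 and 6.23), SPRR1B (-5.74; -5.83 and -0.09), SPRR3 (-5.69; -2.6 and 3.09), C3 (-5.50; -5.03 and 0.47), IL1A (-4.84; -5.33 and -0.5), LYZ (-4.09; 0 and 4.09) and GFPT1 (-2.64; -1.29 and 1.35). Leaving out 1 sample could end the calls of ID4, S100P, GCLM, TXN and GFPT1. Without probe sets ending in _x_at or _s_at the calls of IL1A (0.27), FN1 (-0.54) and COL6A1 (0.03) were lost, and other alternatives ended those of PROM1, ID4, S100P, GCLM, TXN and GFPT1 (adjusted p from 0.0511 to 0.307).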

How the results depend on the processing

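Tests with the GAPDH 3-prime to 5-prime covariate, and those without both normal samples in which that difference was largest, were chosen only after seeing the data.

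Of 314 gene results in the 8 comparisons, 164 kept their direction and their side of the threshold under every alternative run for them. At least 1 alternative ended the call of 130, gave a call to 15 and reversed the direction of 9. Over genes and alternatives, 6303 values were the same in this sense, 677 lost and 27 gained a call, and 9 reversed. Without probe sets ending in _x_at or _s_at the reversed values were POSTN 0.02 (BerEp4+ against CD10+), COL3A1 -0.03 and FN1 -0.04 (stroma), IL1A -0.3 and EGFR -0.14 (HMEC lines against epithelium), ERBB3 -0.04 (effusion against epithelium), EGFR 0.02 (cancer against HMEC lines) and IL1A 0.27 (last comparison), because another probe set then stood for the gene. With the median over probe sets ESR1 reversed in effusion against epithelium (-0.03). In HMEC lines SLC7A11 was 0.77 with that median.

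Counts of genes past the threshold moved by more than 1.5 times in these cases. Without probe sets ending in _x_at or _s_at, which leaves 8351 genes, they were 663 (BerEp4+ against CD10+), 436 (cancer against HMEC lines), 46 (effusion against lines) and 481 (last comparison). With array weights they were 1949 (BerEp4+ against CD10+), 3279 (stroma), 56 (effusion against lines) and 206 (triple-negative against receptor-positive), and the cause was not tested. With only the compared samples they were 1403 (effusion against epithelium), 457 (cancer against HMEC lines) and 48 (effusion against lines), and with all 26 samples 401 (triple-negative against receptor-positive), where the number of samples behind the spread changed. With HMEC lines averaged by laboratory, which leaves fewer samples, they were 780 (HMEC lines against epithelium), 163 (cancer against HMEC lines) and 289 (last comparison). Without both HER2-amplified lines 33 genes passed between triple-negative and receptor-positive lines (2 higher, 31 lower), from fewer samples. With the GAPDH covariate 747 passed in stroma and 157 between triple-negative and receptor-positive lines, and without both normal samples 820 in stroma; the cause was not tested.

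Leaving out 1 sample at a time gave 536 to 1213 genes for BerEp4+ against CD10+, 655 to 1490 for stroma, 1454 to 2481 for HMEC lines and 1455 to 2388 for effusion tumours against epithelium, 435 to 779 for cancer against HMEC lines, 37 to 232 for effusion tumours against lines, 36 to 128 for triple-negative against receptor-positive lines and 435 to 857 for the last comparison. The SLC7A11 difference between triple-negative and receptor-positive lines was 0.14 to 1.4, 1.19 with T74D counted as receptor-positive (exact permutation p = 0.365) and 0.6 with the median over probe sets (p = 0.492), and passed under none of these.

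The donor as a replicate block gave 935 genes for BerEp4+ against CD10+ and 1163 for stroma, and as a random block 1162 for stroma, 2296 for HMEC lines, 2275 for effusion tumours and 767 for the last comparison. Of the genes passing without it, 891 of 997 and 1134 of 1249 also passed with the replicate block. Among the gene results checked, it changed 5 of 79 (MUC1, adjusted p = 0.0644; PDGFRA, 0.0582; GMPS, 0.0542; WFDC2, 0.0615; SERPINB5, 0.0629), and the random block 1 of 163 (SERPINB5, 0.054). It changed no other of these gene results, and among the lists the replicate block gave adipocyte genes a call in stroma (0.0494). Deviations from the group mean correlated at 0.162 to 0.222 in the 3 pairs of a BerEp4+ and a stromal sample of 1 donor, against -0.189 to 0.021 in 6 pairs of different donors. Between CD10+ and stromal samples they were -0.086 to 0.089 within and -0.112 to 0.172 between donors, and between BerEp4+ and CD10+ samples -0.193 to 0.04 and -0.194 to 0.269. Of the stroma splits, 27 part the donors as the real one does.

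List calls lost, or gained without 1 sample, are given with the lists. Under the other alternatives 21 of 70 calls were lost at least once (68 of 804 tests). Of 154 lists without a call 31 gained one (62 tests). With an estimated correlation most calls were lost, and 0 to 3 per comparison held. Signal near background limits dim genes, and arrays give no depth beyond this.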

Other observations

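The test of whether amino acid response or NRF2 target genes move with SLC7A11 was set down before its result was seen, after the spread of SLC7A11 between lines had been noticed, and no test in this part was chosen after its result was seen.

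Stroma and epithelium also differed in genes not described above. SFRP4, an inhibitor of Wnt signalling, was higher in stroma (4.74 ± 0.1). In effusion tumours GPD1L, an enzyme of glycerol metabolism, rose by 4.67 ± 0.7 against epithelium, and PROM1 (-6.17 ± 1.6), CRYAB, a small heat shock protein (-6.15 ± 1.13), and ANXA1, an annexin (-6.05 ± 1.16), were lower.

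The line labelled T74D was left out of the comparison of line classes, except in the 1 alternative that counted it as receptor-positive. It measured 10.86 in ESR1 (receptor-positive lines 9.76 to 11.84, triple-negative lines 4.26 to 6.98), 5.23 in SLC7A11, 4.92 in GCLM (4.74 to 6.84 and 6.5 to 8.03) and 11.63 in GLUL.

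SLC7A11 varied between the 10 cancer lines, from 5.23 to 10.62. NRF2, which is active under oxidative stress, and ATF4, which is active when amino acids are short, both induce SLC7A11, so their target genes may move with it. Over the 10 lines the mean of the NRF2 target list correlated with SLC7A11 at r = 0.537 (p = 0.105, adjusted p = 0.211; rank correlation 0.345, p = 0.332), and at 0.387 without both lines farthest from the others, too few lines to tell. The mean of the amino acid response list correlated at -0.402 (p = 0.25, adjusted p = 0.25; rank correlation -0.503, p = 0.144), and at 0.105 without both lines farthest from the others, where its sign turned. This argues against a strong rise of these genes with SLC7A11 over all 10 lines, and a weak relation in either direction stays open.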
